A study of Mus musculus with 6 samples.

How the data were processed

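Total RNA from the primary calvaria (the skull roof) of FVB/N mice at postnatal day 3 was measured on Illumina mouse bead arrays with biotin-labelled RNA, per the labels. The 6 arrays form 2 groups: 3 wild-type samples (WT) and 3 samples with a gain of function of the microRNA miR-34c (TG). The labels call the arrays biological replicates WT1 to WT3 and TG1 to TG3 and do not state whether each is a single pup or a pool, nor the sex.

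The non-normalised table deposited by the authors held, per probe and array, an intensity on a linear scale without background subtraction and a detection p-value, per the file headers. It also held 974 control rows without an identifier, of which the last 936 were taken as negative controls because detection p-values recomputed from them differed from the deposited p-values by at most 0.00695 on any array. In that control block, per the file headers, the arrays carry replicate numbers 4 to 6 and an age label other than that of the sample labels; the columns of the probe table were used under the names given in the sample labels, and the discrepancy is unresolved. The values the authors normalised were deposited on a log2 scale for the same probes; the submitters' processing notes name lumi, and the version, background step, transformation and normalisation are not given in the sources used here. Each array's deposited log2 values had a median of 7.55; their slope against log2 intensity was 0.995 to 1.03 for bright probes and 0.591 to 0.705 for dim probes, so fold changes of dim probes are compressed in them.

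Gene symbols came from the platform annotation given for the array. Of 45281 probes, 34885 had 1 symbol, 18 had several and 10378 were not named here. The Entrez identifiers of 34807 named probes were found in a RefSeq table used for names, and 0 symbols changed. No genomic position is given because the files name no genome build.

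Intensities were background-corrected with limma 3.58.1 in R 4.3.3 by the normal-exponential method with negative controls, an offset of 16 was added, and arrays were quantile-normalised on the log2 scale. Probes with a detection p-value under 0.05 on at least 3 of the 6 arrays, whatever the group, were tested, which left 20632 probes; 17702 of them were named and stood for 11204 genes. TG was compared with WT by limma's linear model with empirical Bayes moderation, two-sided, with Benjamini-Hochberg adjustment over the probes tested and a threshold of 0.05. A gene was represented by its tested probe with the highest mean over all arrays. Log2 fold changes are TG minus WT, with standard errors (SE) from the fit; group values are means ± SD of normalised log2 intensity, n = 3. Where a probe was not detected on any array of a group, the fold is given as "at least", from the other group's mean over the dim group's mean of, per array, the higher of the probe's own value and the lowest detected signal.

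Before the data were examined, 32 gene lists, the tests, the alternatives and the rule for named genes were fixed. The rule took the 12 genes with the largest fold in each direction among probes past the threshold with no overlap of the groups, filled where fewer passed to 6 per direction by smallest unadjusted p; up to 4 members per list with the smallest p; and 21 key genes of bone, Notch signalling and the cell cycle, not all of which are reported here. Lists were tested with limma's camera at a preset inter-gene correlation of 0.01, two-sided, adjusted over 30 lists; the sex-linked list was kept out of that family, and the melanocyte list, with 4 measured members, was below the minimum of 5. Camera with an estimated correlation and fry were the alternatives. Other alternatives were no background correction, the authors' values, median scaling, cyclic loess, no filter or a stricter filter on dim probes, an offset of 50, replicate number as a block, trended and robust variance, array weights, Y-linked signal (the mean of the Kdm5d and Uty probes) as a covariate, the mean of a gene's probes, a looser criterion and leaving out each array. The male-pattern arrays alone and the muscle list as a covariate were chosen after seeing the data. Mean shifts of the called lists with and without the Y-linked covariate, with SE, come from a linear model on the list mean per array, also added after seeing the data. A planned test of transcripts with miR-34c seed sites was not run, because untranslated-region sequences were not used here.

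The pipeline was tested on simulated data with the spread of these arrays, 20632 probes, 3 against 3 arrays and 200 changed probes in each of 20 runs. It recovered 7.4% of probes changed 1.5-fold, 62.0% of those changed 2-fold, 93.0% at 3-fold and 96.7% at 4-fold, with a mean of 7.4 false calls per run. Noise was drawn independently for each probe, without differences shared by the probes of an array, and 50 probes at each fold were changed together. The shares recovered therefore need not hold for the real arrays. In 100 simulated runs with an unchanged list of 30 genes and a residual correlation of 0.5, camera with the preset correlation gave p under 0.05 in 45.0% of runs, and with an estimated correlation in 4.0%. The number of arrays limits the precision: the median 95% interval of a log2 fold change extended 0.34 to either side.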

Results

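Gene expression was measured on 6 bead arrays of calvarial RNA from FVB/N mice at postnatal day 3, with 3 wild-type (WT) samples and 3 samples carrying a gain of function of miR-34c (TG). The comparison asked which calvarial transcripts differ when this microRNA, a small RNA that represses matching messenger RNAs, is raised in the osteoblast setting named by the series title. Median intensity per array was 125.1 to 132.6, and 19680 to 21412 probes were detected at a detection p under 0.05. Arrays of the same group correlated at r of 0.982 to 0.989 across probes, and arrays of different groups at 0.980 to 0.989. At most 0.46% of probes had identical intensities on any pair of arrays, so no array was a copy of another.

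In TG calvaria, the osteocalcin genes, which encode an abundant bone matrix protein of mature osteoblasts, had lower measured values than in WT on all 3 arrays. Bglap had 12.94 ± 0.26 in TG against 13.72 ± 0.21 in WT (SD, n = 3), a log2 fold change of -0.78 ± 0.17 (SE; 95% interval -1.18 to -0.39), and Bglap2 had 13.78 ± 0.22 against 14.48 ± 0.40. Of the main collagen genes of bone, Col1a2 had a log2 fold change of 0.03 ± 0.15 (SE) at 12.63 ± 0.21 in WT. The Col1a1 probe, at 15.21 ± 0.11 in WT, lies near the top of the intensity range, so its 0.03 carries little information. No gene passed the test over all probes, so these are values and not calls. With limma, 0 of 20632 probes and 0 of 11204 genes had an adjusted p under 0.05, and the smallest adjusted p was 0.9996. At an unadjusted p under 0.05 there were 710 probes, 359 higher and 351 lower in TG, where chance alone would give 1031.6; these probes represented 284 genes by their brightest probe. The groups did not overlap for 747 probes higher and 810 lower in TG, together 7.55% of probes against 10% by chance. Differences of at least 1.5-fold were measured for 136 probes and of at least 2-fold for 9, of which 6 had an unadjusted p under 0.05. Trended and robust variance in limma also gave 0 probes, with 550 at an unadjusted p under 0.05.

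Among the probes with the smallest p, Eya2, a transcriptional co-activator and phosphatase, had 4.87 ± 0.09 in TG against 5.70 ± 0.07 in WT, a log2 fold change of -0.83 ± 0.11 (limma, unadjusted p = 8.83e-05, adjusted p = 0.9996). Jam2, a junctional adhesion molecule, had -0.67 ± 0.12, and its other probes had -0.63, -0.43 and, on the brightest, -0.10. Ppm1l had -0.63, Kif16b, a kinesin motor, had -0.65, and the Y-linked Uty had -0.67. A Sox6 probe that was not detected on any TG array was at least 1.40-fold lower there, while the other Sox6 probes had 0.04 to 0.41. On the higher side, Cct7, a subunit of the cytosolic chaperonin, had a log2 fold change of 0.58 ± 0.12, Eml5 had 0.67 ± 0.16 and Alkbh8 had 0.59 ± 0.15. Probes of Gnaq, Lrba and Nxph4 were not detected on any WT array and were at least 1.27-fold, 1.22-fold and 1.32-fold higher in TG. Other probes of Gnaq (-0.07 to 0.22), Lrba (-0.02 and 0.09), Ppm1l (-0.01 and 0.22) and Alkbh8 (0.09) did not show the difference. The values of dim probes depended on the background step: without background correction Eya2 had -0.23, Jam2 -0.37, Cct7 0.17 and Gnaq 0.22. The Eya2 and Ppm1l probes were each detected on only 1 TG array, and the Eml5 probe on only 1 WT array.

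**Figure D1:**
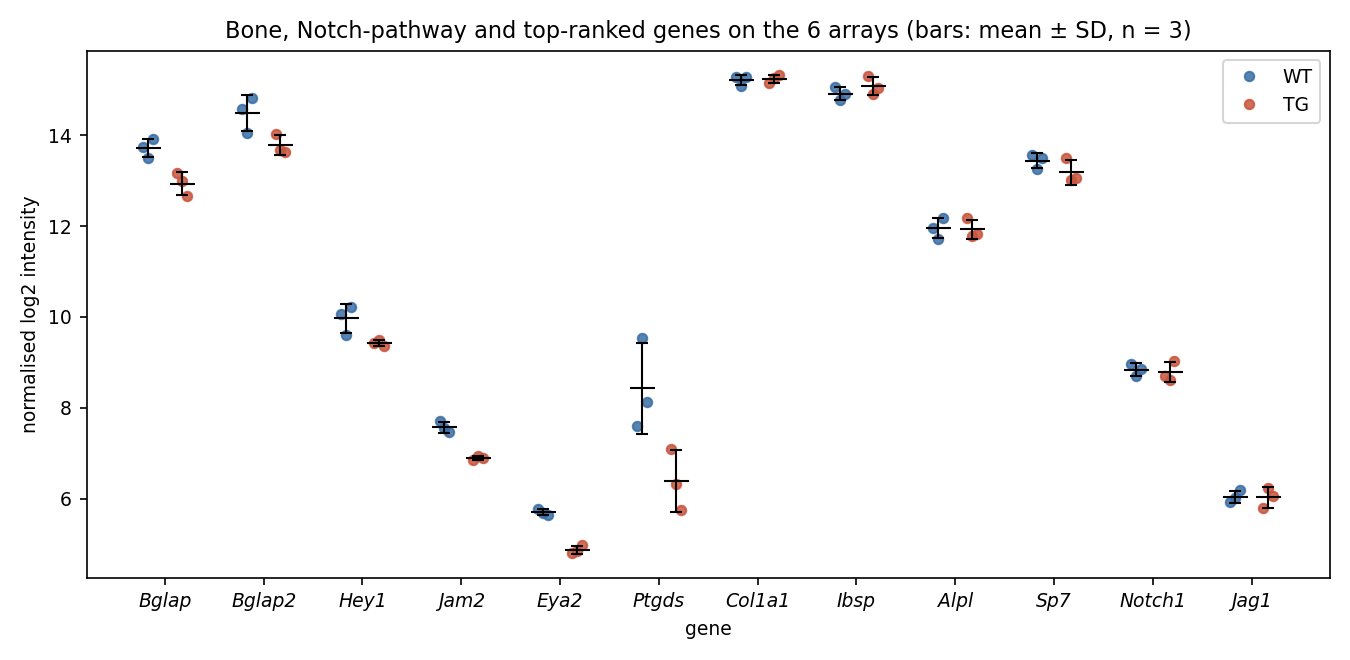
Normalised log2 intensity (vertical axis) of 12 genes (horizontal axis) on the 3 WT and 3 TG arrays; points are arrays, and bars give the mean ± SD of n = 3. The TG points of Bglap, Bglap2, Hey1, Jam2, Eya2 and Ptgds lie below the WT points, with adjusted p of 0.9996 in limma, and those of Col1a1, Alpl, Notch1 and Jag1 overlap them. Jam2 is shown by its probe with the smallest p, while its brightest probe had a log2 fold change of -0.10 with overlapping groups.

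Of the bone matrix and mineralisation list, 31 genes were measured, 17 with positive and 14 with negative log2 fold changes, and no shift was called (camera, adjusted p = 0.661). The list mean was 0.003 ± 0.11 in TG against -0.003 ± 0.10 in WT (SD, n = 3), so a small shift either way is not excluded. Besides osteocalcin, Ibsp, encoding bone sialoprotein, had 0.17 ± 0.14 (SE), Alpl, encoding tissue-nonspecific alkaline phosphatase, had -0.03 ± 0.17, Col11a2 had 0.39 ± 0.18 and Mmp16 had 0.32 ± 0.16, but the other probe of each had the opposite sign, at -0.18 for Col11a2 and -0.13 for Mmp16. The Ibsp probe, at 14.91 ± 0.14 in WT, lies near the top of the intensity range, and Ibsp probes at 13.95 and 14.49 in WT had 0.20 and 0.13. Bglap had an adjusted p of 0.0547 in limma adjusted over the list alone, so 0 members passed there too. The second Bglap probe had -0.96 ± 0.26; Bglap and Bglap2 are near-identical copies whose probes may share signal, so the probes are not independent. TG arrays with a female sex-linked pattern had the lower Bglap values, 12.99 and 12.66, against 13.16 on the TG array with a male pattern; with Y-linked signal (the mean of Kdm5d and Uty) as a covariate the log2 fold change was -0.48 (limma, unadjusted p = 0.0868). Osteoblast transcription factors had 5 positive and 11 negative values among 16 (camera, adjusted p = 0.101), with Alx4 at -0.33 ± 0.13 (its other probe at -0.02), Dlx5 at -0.45 ± 0.22 and Sp7, which osteoblast differentiation requires, at -0.25 ± 0.17, a value that turned to 0.16 with the Y-linked covariate and 0.06 with the male-pattern arrays alone. Dlx5 had -0.61 to -0.22 on leaving out 1 array. Collagen processing and secretion had 15 positive and 14 negative (adjusted p = 0.771), with Plod2, a collagen lysyl hydroxylase, at 0.32 ± 0.16 and its other probes at 0.18 and -0.28. Osteocyte markers had 3 positive and 13 negative (adjusted p = 0.0995), with the potassium channel gene Kcnk2 at -0.78 ± 0.22, Wnt1 at -0.38 ± 0.16, Phex at -0.28 ± 0.16 and Dmp1 at -0.32 ± 0.24. Osteoclast markers had 4 positive and 20 negative (adjusted p = 0.0817), with Car2, a carbonic anhydrase, at -0.61 ± 0.20, Ocstamp at -0.32 ± 0.12, Acp5 at -0.09 ± 0.22 and Ctsk at -0.08 ± 0.16. The Ocstamp probe was dim (5.18 in WT, 4.86 in TG) and detected on only 1 TG array. Its log2 fold change ranged from -0.32 to -0.06 over the alternatives other than leaving out arrays. The Wnt1 probe, also dim, was detected on 2 TG arrays. Of the osteoclast-regulating factors 8 were measured (adjusted p = 0.958), with Tnfsf11, encoding RANKL, at -0.05 ± 0.27 and its decoy receptor gene Tnfrsf11b at 0.13 ± 0.21. Runx2 and Spp1 had no named probe here.

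The Notch pathway list, a signalling route that reported miR-34 targets belong to, had 9 positive and 21 negative log2 fold changes among 30 measured genes, with a median of -0.06 (camera, adjusted p = 0.148). The Notch effector gene Hey1 had 9.43 ± 0.07 in TG against 9.97 ± 0.32 in WT, a log2 fold change of -0.54 ± 0.17 with no overlap of the arrays, and an adjusted p of 0.387 in limma adjusted over the list alone. A dim probe of Maml2, a Notch coactivator gene, chosen after its values were seen, went the other way without overlap, at 6.15 ± 0.28 in TG against 5.28 ± 0.49 in WT (log2 fold change 0.87), while the brightest Maml2 probe had 0.12. The receptor gene Notch1 had -0.06 ± 0.15 and the ligand gene Jag1 -0.02 ± 0.15, while Notch2 was not detected on enough arrays to be tested. The list of reported miR-34 family targets had 11 positive and 29 negative values among 40, also with a median of -0.06 (adjusted p = 0.146). Among these, Pdgfra had -0.32 ± 0.15, Numbl -0.31 ± 0.15, Cdk4 -0.19 ± 0.11, Ccnd1 0.04 ± 0.13 (its other probes -0.17 and -0.10) and Cdk6 0.21 ± 0.14. The p53 targets had 7 positive and 16 negative among 23 (adjusted p = 0.0995), with Gadd45a at -0.50 ± 0.24 on its brightest probe and 0.00 on the other.

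Ribosomal protein transcripts were slightly higher in TG as a group. Of 57 measured, 46 had positive log2 fold changes with a median of 0.07 (camera, adjusted p = 0.00234; adjusted p = 0.436 with an estimated correlation), no member passed, and Rps25 had 0.35 ± 0.14 and Rpl19 0.23 ± 0.11. The estimated correlation of this list was 0.0043, below the preset 0.01, so a higher correlation among its genes did not end the call. Its unadjusted camera p was 0.000234 with the preset correlation and 0.0145 with the estimated one. Leaving out TG replicate 2 ended the call (ribosomal proteins, adjusted p = 0.0793), as did Y-linked signal as a covariate (0.431). Cell cycle and DNA replication had 15 positive and 32 negative among 47 (adjusted p = 0.374), with Ccnd2 at 0.57 ± 0.29 (0.29 to 0.89 on leaving out 1 array, and -0.15 with Y-linked signal as a covariate) and Mcm7 at -0.19 ± 0.12 (its other probe at 0.14). Mitochondrial oxidative phosphorylation had 34 positive and 40 negative (adjusted p = 0.732), with Ndufb4 at 0.41 ± 0.16. The Wnt pathway had 18 positive and 22 negative (adjusted p = 0.507), with the secreted Wnt inhibitor gene Wif1 at -0.40 ± 0.16 (-0.09 with the Y-linked covariate) and the receptor gene Fzd8 at 0.38 ± 0.16. The BMP and TGF-beta pathway had 24 positive and 18 negative (adjusted p = 0.932), with Nog at -0.38 ± 0.22 (-0.55 to -0.16 on leaving out 1 array). The FGF, IGF and hedgehog pathway had 18 positive and 7 negative (adjusted p = 0.514), with Igfbp2 at 0.68 ± 0.22, which was 0.06 with the Y-linked covariate. The fibrous extracellular matrix list had 21 positive and 18 negative (adjusted p = 0.514), with Mfap4 at 0.48 ± 0.21 and Postn, encoding periostin, at 0.40 ± 0.19, with its other probes at -0.29 and -0.14. The unfolded protein response had 13 positive and 10 negative (adjusted p = 0.514), with the chaperone gene Hspa5 at 0.39 ± 0.27 (0.11 to 0.71 on leaving out 1 array). Interferon-stimulated genes had 11 positive and 7 negative (adjusted p = 0.804), with Rsad2 at -0.80 ± 0.27, Bst2 at -0.37 ± 0.14 and Stat2 at 0.34 ± 0.11; their median of 0.08 and mean of -0.03 differed in sign. Immediate-early and heat-shock genes had 10 positive and 14 negative (adjusted p = 0.632), with Atf3 at -0.31 ± 0.14.

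Transcripts of tissues next to the calvarial bone differed between single arrays. Chondrocyte markers were higher in TG as a list, with 21 of 22 members positive (camera, adjusted p = 0.000137; adjusted p = 0.806 with an estimated correlation). Col10a1, the collagen of hypertrophic cartilage, had 11.35 and 8.86 on TG replicates 2 and 3, 7.51 on WT replicate 2 and 4.72 to 4.89 on the other arrays, and Col2a1, the main cartilage collagen, had a log2 fold change of 0.26 ± 0.20. The Col2a1 probe, at 14.84 ± 0.33 in WT and 15.11 ± 0.25 in TG, lies near the top of the intensity range, so its value carries little information. Without TG replicate 2 the chondrocyte markers had an adjusted p of 0.264, and without WT replicate 3 of 0.550. Y-linked signal as a covariate also ended the call of the chondrocyte markers (0.832), where the mean shift went from 0.42 ± 0.40 (SE) to 0.02 ± 0.66, and with the male-pattern arrays alone their direction turned (0.997). Neutrophil and myeloid progenitor markers were lower in TG as a list, with 18 of 20 members negative (adjusted p = 0.000802; adjusted p = 0.806 with an estimated correlation), among them Mpo, encoding myeloperoxidase, at -0.999 ± 0.35 (its other probes at -0.84 to -0.15) and Elane, encoding neutrophil elastase, at -0.39 ± 0.23. The Elane probe was dim and detected on only 1 TG array. The list mean of TG replicate 1 was -0.84 relative to all arrays, and without it the direction of the neutrophil and myeloid progenitor markers turned (adjusted p = 0.992); without WT replicate 1 the adjusted p was 0.0766. With Y-linked signal as a covariate the neutrophil and myeloid progenitor markers stayed lower (camera with the preset correlation of 0.01, adjusted p = 3.71e-15). The residual correlation of this list was 0.52, above the preset value, so that adjusted p may be far too small. The mean shift of the list over arrays went from -0.37 ± 0.35 (SE) to -1.08 ± 0.35. Its 95% interval with the covariate, on 3 residual degrees of freedom, was -2.20 to 0.03 and so spans both signs. The covariate fit rests mainly on TG replicate 1. Erythroid markers were lower in TG, with 10 of 14 negative (adjusted p = 0.0128; adjusted p = 0.806 with an estimated correlation), including Slc4a1, the red cell anion exchanger, at -1.38 ± 0.72, whose WT values were 9.45, 7.35 and 5.98. The erythroid markers had an adjusted p of 0.419 without WT replicate 2, 0.0678 without TG replicate 1 and 0.0793 without TG replicate 2. With fry, 0 of the 30 lists passed, with a smallest adjusted p of 0.322, against 4 with the preset correlation and 0 with an estimated one.

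**Figure D2:**
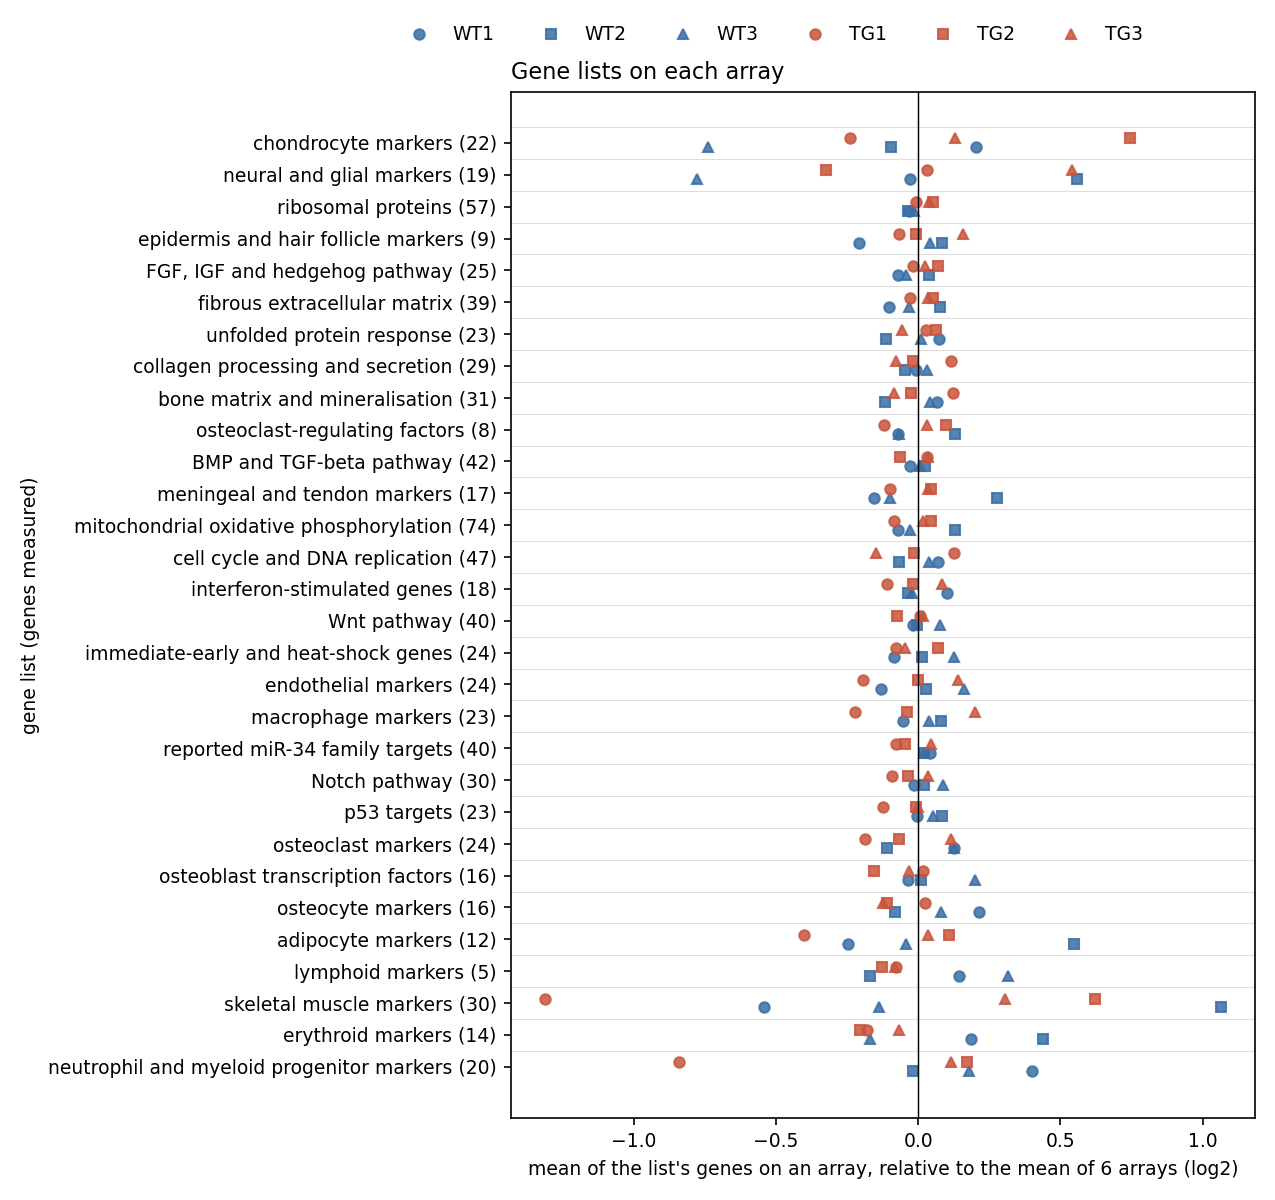
Mean log2 deviation of each gene list from its average over the 6 arrays (horizontal axis) for 30 lists (vertical axis, genes measured in parentheses); symbols stand for replicates, blue for WT and red for TG. Skeletal muscle markers range from -1.31 on TG replicate 1 to 1.06 on WT replicate 2, and chondrocyte markers from -0.74 on WT replicate 3 to 0.74 on TG replicate 2.

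Skeletal muscle markers had 5 positive and 25 negative log2 fold changes among 30 (camera, adjusted p = 0.0765), with Pvalb at -0.81 ± 0.66 and Casq2 at -0.56 ± 0.49. Leaving out single arrays changed that outcome in 5 of 6 cases: without TG replicate 1 the skeletal muscle markers turned to higher (adjusted p = 0.00656), and they passed as lower without WT replicate 1 (2.43e-05), WT replicate 3 (0.0134), TG replicate 2 (3.8e-07) or TG replicate 3 (0.00126). Their list means were -0.54, 1.06 and -0.14 on the WT arrays and -1.31, 0.62 and 0.31 on the TG arrays, a spread within each group that exceeded the difference between the groups. Adipocyte markers had 1 positive and 11 negative (adjusted p = 0.146), with Adipoq, encoding adiponectin, at -0.57 ± 0.30 on a dim probe detected on 2 arrays of each group. Neural and glial markers had 14 positive and 5 negative (adjusted p = 0.514), with Nefm at -0.57 ± 0.30 (-0.81 to -0.20 on leaving out 1 array). The Nefm probe was dim and detected on only 2 WT arrays and 1 TG array. Meningeal and tendon markers had 12 positive and 5 negative (adjusted p = 0.302), a median of 0.10 and a mean of -0.01, and Ptgds, a prostaglandin D synthase gene of the meninges, had 6.38 ± 0.68 in TG against 8.42 ± 1.00 in WT, a log2 fold change of -2.04 ± 0.50 that was -1.20 without background correction. Macrophage markers had 9 positive and 14 negative (adjusted p = 0.302), with Adgre1 at -0.34 ± 0.16 on its brightest probe and 0.08 on the other. Lymphoid markers had 1 positive and 4 negative (adjusted p = 0.233), with Igll1 at -0.45 ± 0.29. Endothelial markers had 9 positive and 15 negative (adjusted p = 0.302), with Sox17 at -0.54 ± 0.14 and a second Sox17 probe at -0.07. Epidermis and hair follicle markers had 6 positive and 3 negative (adjusted p = 0.487), with Aqp3 at 0.20 ± 0.13 on a dim probe detected on only 1 WT array. The 4 melanocyte markers measured had -0.07 to 0.07, and Tyr was not detected on enough arrays to be tested.

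Xist and Kdm5d divided the TG group, and Uty did not. Xist, the RNA that coats the inactive X chromosome in females, had 9.17 and 9.34 on TG replicates 2 and 3, 4.69 on TG replicate 1 and 4.49 to 5.12 on the WT arrays. The Y-linked Kdm5d had 4.69 and 4.43 on TG replicates 2 and 3 against 7.17 on TG replicate 1 and 6.99 to 7.36 in WT. The Y-linked Uty, on a dim probe, had 5.36 on TG replicate 1, near the 5.14 on each of the other TG arrays and below the 5.73 to 6.07 of the WT arrays, so it separated TG from WT. By Xist and Kdm5d, the WT arrays and TG replicate 1 had a male pattern and the other TG arrays a female one, and no WT array had the female pattern. Without TG replicate 1, limma called 2 probes, Xist higher and Kdm5d lower. All 3 sex-linked genes measured passed adjusted over the list alone, which was kept apart from the other lists. The first principal component held 35.4% of the variance and placed WT replicates 1 and 3 and TG replicate 1 on the side opposite to the remaining arrays.

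**Figure D3:**
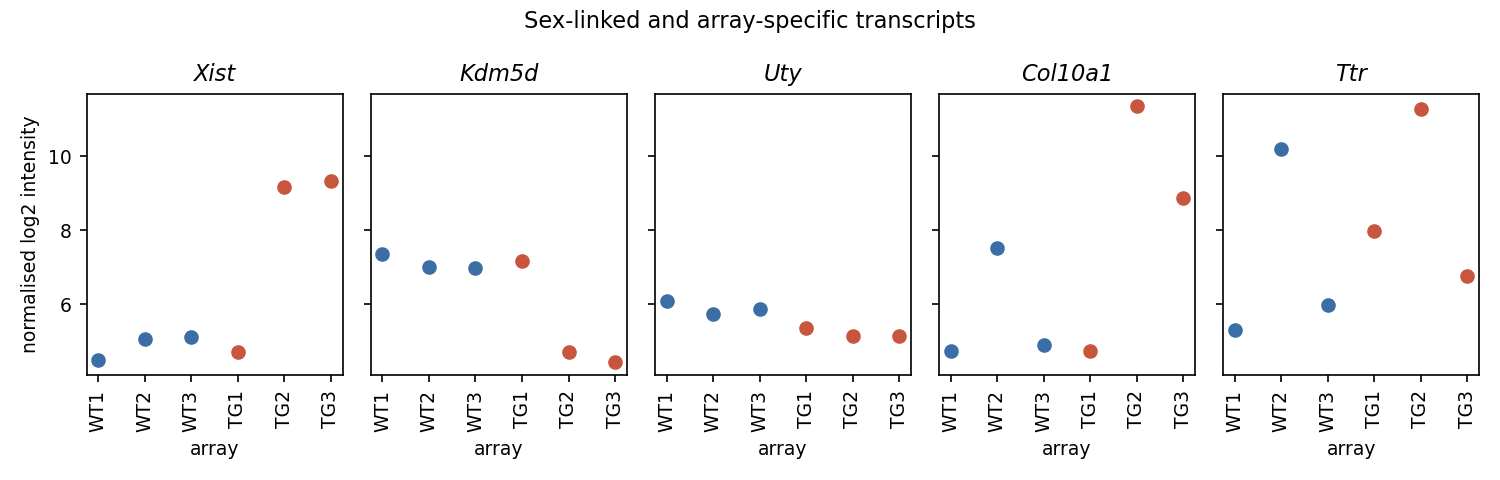
Normalised log2 intensity (vertical axis) of 5 transcripts on each array (horizontal axis), blue for WT and red for TG. Xist is above 9.0 and Kdm5d below 5.0 on TG replicates 2 and 3, and Col10a1 and Ttr differ between arrays of the same group.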

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

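The male-pattern arrays alone and the muscle covariate were chosen after seeing the data; the other alternatives were planned, and the cause of the changes given here was not tested unless stated. Limma called 0 probes in each fit that kept all arrays and with the male-pattern arrays alone, and leaving out single arrays gave 0 to 2 for probes and for genes, the 2 being Xist and Kdm5d without TG replicate 1. Unadjusted p under 0.05 was reached by 457 probes with the stricter filter (16004 tested) to 1780 without a filter (every probe tested), and by 1162 with Y-linked signal as a covariate, against 710; the looser criterion of an unadjusted p under 0.05 with at least 1.5-fold gave 76 probes. Of 144 named genes with 2838 values under alternatives, 109 kept their sign throughout; on leaving out at least 1 array 18 genes had the other sign and 58 moved by more than a factor of 2 in log2 fold change. Over all alternatives 83 values had the other sign and 2 passed; a sign change of a value that passed in neither fit was not counted as a reversal. Of 688 values for 30 lists, 611 kept their call, 26 lost it, 46 gained it and 5 changed direction. Each of these 5 passed in the main or the alternative fit but not in both, so none was a call in both directions. The counts lost and gained leave them out. Signal over background limited the dim probes, whose fold changes shrank in the authors' values (Eya2 -0.17, Jam2 -0.31, Ptgds -1.03) while Bglap kept -0.78.

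With an estimated correlation the 4 called lists had adjusted p of 0.806 for chondrocyte markers, erythroid markers and neutrophil and myeloid progenitor markers and 0.436 for ribosomal proteins. With fry these were 0.935 (directional) and 0.962 (mixed) for the former lists and 0.322 and 0.481 for ribosomal proteins. Over all alternatives other than leaving out arrays, adjusted p ranged from 4.41e-06 to 0.997 for chondrocyte markers, 0.00279 to 0.962 for erythroid markers, 1.48e-21 to 0.962 for neutrophil and myeloid progenitor markers and 1.17e-07 to 0.481 for ribosomal proteins. Erythroid markers lost their call in the authors' values (0.0767), with the stricter filter (0.155) and with the Y-linked covariate (0.0864; mean shift -0.30 ± 0.18 (SE) before and -0.35 ± 0.33 after, so the shift stayed and its SE grew). Median scaling ended that of ribosomal proteins (0.0793) and added osteocyte markers (0.0472), osteoclast markers (0.0224) and skeletal muscle markers (0.00279), all lower. Without a filter osteoclast markers passed, lower (0.0366).

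Whether the replicate numbers pair the samples was not settled. Same-numbered deviations correlated at 0.26, 0.15 and -0.17, and not every sample correlated best with its own number. These correlations are few and also carry the tissue differences between arrays, so they neither show nor exclude pairing. With replicate number as a block, limma called 0 probes, with 789 at an unadjusted p under 0.05, and osteoblast transcription factors (0.0399), skeletal muscle markers (3.54e-06) and adipocyte markers (0.0324) passed, lower; no other call changed.

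With Y-linked signal as a covariate, chondrocyte markers (0.832; mean shift 0.42 ± 0.40 (SE) before and 0.02 ± 0.66 after) and ribosomal proteins (0.431; 0.06 ± 0.02 and 0.02 ± 0.02) lost their calls, cell cycle and DNA replication turned to higher (0.00417), collagen processing and secretion passed, higher (0.00936), and these passed, lower: osteoclast markers (0.00109), Notch pathway (0.00936), p53 targets (0.00919), skeletal muscle markers (3.1e-30), macrophage markers (8.64e-05), endothelial markers (9.42e-06), adipocyte markers (0.000145) and mitochondrial oxidative phosphorylation (0.0176). With the male-pattern arrays alone, where the lone TG array is assumed to vary like WT, chondrocyte markers turned to lower without passing (0.997), ribosomal proteins lost their call (0.322), cell cycle and DNA replication turned to higher (0.0289), collagen processing and secretion passed, higher (0.0163), and these passed, lower: osteoclast markers (0.000252), Notch pathway (0.0138), reported miR-34 family targets (0.0364), p53 targets (0.0133), skeletal muscle markers (1.48e-21), macrophage markers (0.000353), endothelial markers (0.000252) and adipocyte markers (0.00419). Both fits rest mainly on TG replicate 1 and use the preset correlation, and the covariate includes Uty, which separates the groups. With Y-linked signal as covariate the neutrophil and myeloid progenitor markers kept their call (3.71e-15 with the preset correlation). Their mean shift over arrays went from -0.37 ± 0.35 (SE) to -1.08 ± 0.35. The 95% interval of the latter, on 3 residual degrees of freedom, was -2.20 to 0.03 and so spans both signs. Among named genes, that covariate brought Igfbp2 to 0.06, Wif1 to -0.09, Wnt1 to -0.07 and Atf3 to -0.03, and Kcnk2 to -1.26 and Car2 to -1.01. With the muscle covariate, osteoblast transcription factors (0.022) and osteocyte markers (0.0148) passed, lower.

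Leaving out single arrays gave these ranges of adjusted p: chondrocyte markers 2.31e-11 to 0.550, neutrophil and myeloid progenitor markers 1.85e-07 to 0.992 (direction turned without TG replicate 1), erythroid markers 0.000137 to 0.419, ribosomal proteins 0.00381 to 0.0793, skeletal muscle markers 3.8e-07 to 0.173 (higher, 0.00656, without TG replicate 1), osteoblast transcription factors 0.0167 to 0.649, osteocyte markers 0.00502 to 0.516, osteoclast markers 0.000112 to 0.794, Notch pathway 0.0157 to 0.789, reported miR-34 family targets 0.0215 to 0.610, p53 targets 0.0320 to 0.594, cell cycle and DNA replication 0.00656 to 0.826, neural and glial markers 0.00502 to 0.611, macrophage markers 0.00174 to 0.669, lymphoid markers 0.0338 to 0.619, endothelial markers 0.00475 to 0.567 and adipocyte markers 0.0165 to 0.836. The seed-site test was not run under any setting. A gene's mean over probes was run for genes and lists only, and some dim named genes gave no value with the stricter filter.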

Other observations

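The tests of explanations in this part and the fit to the male-pattern arrays alone were chosen only after the results they bear on had been seen; the splits and the fits with an estimated correlation and with Y-linked signal as a covariate were planned. The transcripts outside the gene lists given here were chosen after their values were seen. Ttr, Sst and Slc17a6 ranged more widely within each group than between the group means. Ttr, encoding transthyretin, which the choroid plexus secretes, had 10.18 on WT replicate 2 and 11.27 on TG replicate 2 against 5.30 to 7.97 on the other arrays. The neuropeptide gene Sst had 8.17 on TG replicate 3 and 4.58 to 6.14 elsewhere, and Slc17a6, a vesicular glutamate transporter gene, had 8.02 on TG replicate 3 and 4.96 to 6.94 elsewhere. Slc16a9 had 8.05 ± 0.38 in TG against 7.11 ± 0.61 in WT (SD, n = 3) with no overlap, and Pacsin3 had 5.16 ± 0.31 against 6.09 ± 0.43, also with no overlap, on a dim probe, while the other Pacsin3 probes had log2 fold changes of 0.06 and 0.01; neither gene passed over all probes. An unnamed probe had 11.48 to 11.86 in WT and 11.67 on TG replicate 1, against 9.97 and 9.77 on TG replicates 2 and 3.

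Xist was higher and Kdm5d lower in the TG group. An effect of the transgene in every TG array is argued against by the 1 TG array that lay within the WT range of Xist. The sex of the pups may account for these transcripts, as all 2 arrays with Xist signal also lacked Kdm5d signal. Uty, which was low on all 3 TG arrays, does not follow that division, but its probe is dim, at 5.89 ± 0.17 in WT and 5.21 ± 0.13 in TG. Its log2 fold change ranged from -0.71 to -0.14 over the alternatives other than leaving out arrays, and the cause was not tested. Because no WT array had a female pattern, sex and genotype overlap in this design, and the effect of sex on other genes stays open.

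The osteocalcin probes were lower in TG. The other 29 measured genes of the bone matrix list had a mean shift of 0.059 ± 0.076 (SE over arrays), above -0.39, the bound taken from the Bglap difference. Over the 21 of these genes with a mean between 8 and 15 it was 0.06 ± 0.10, with Ibsp, at 14.91 in WT and 15.08 in TG, still near the top of the range. These values argue against an equal fall of the whole list. The list is not specific to osteoblasts, and cartilage markers differed between arrays, so a smaller share of osteoblasts stays open. The sex of the pups cannot be told apart from genotype for Bglap: with Y-linked signal as a covariate its log2 fold change went from -0.78 to -0.48 (limma, unadjusted p = 0.0868), where the covariate includes Uty, which itself separates the groups, and with the male-pattern arrays alone it was -0.56. Osteoblasts at an earlier stage could give the same pattern; osteocyte markers had a mean shift of -0.14 ± 0.10 (SE) and an adjusted p of 0.806 with an estimated correlation, which leaves this open. An effect of miR-34c on osteocalcin stays open as well, as no probe passed over all tested.

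Markers of neighbouring tissues lay apart between arrays, and unequal amounts of cartilage or marrow in single samples may account for the list calls: the residual correlation was 0.71 among chondrocyte markers and 0.52 among neutrophil and myeloid progenitor markers, whose list means ranged over 0.98 and 1.01 within TG against group differences of 0.42 and -0.37. For erythroid markers the residual correlation of 0.051 decided nothing on unequal amounts of blood. An effect of the transgene on chondrocyte genes stays open, with 1 TG array above all WT arrays in the list mean. With Y-linked signal as a covariate the mean shift of the chondrocyte markers went from 0.42 ± 0.40 (SE) to 0.02 ± 0.66 and the call ended (adjusted p = 0.832). The covariate correlates with genotype (r = -0.77), so the wide SE leaves the sex of the pups open as well, untested for this list. Muscle content may account for the axis of the first principal component, computed without the genes of the muscle list. Its Pearson r with the muscle list mean was 0.95 (exact permutation p = 0.00694, two-sided) and Spearman's rho 0.94 (exact permutation p = 0.0167) over 6 arrays. Without TG replicate 1 and WT replicate 2, r was 0.92, and this was the only relation of this kind computed. Muscle transcripts outside the list were not removed, so the relation may be partly one of muscle transcripts with each other. Adipocyte markers and mitochondrial oxidative phosphorylation had list means in the same order over the 6 arrays as the muscle list. They were lowest on TG replicate 1 (-0.40 and -0.08) and highest on WT replicate 2 (0.55 and 0.13). The axis is therefore not particular to muscle markers and cannot be assigned to muscle content alone.

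The 6 arrays make 10 splits into 3 and 3, too few for a share under 0.1. The real split gave 0 probes past the adjusted threshold, and the highest other split gave 10; against a count of 0 this comparison has no bearing on chance. At an unadjusted p under 0.05 the real split gave 710 probes and the highest other 1936. For lists past the threshold with the preset correlation the values were 4 and 12. In each case 9 of the 10 splits, the real one included, were at least as large as the real count. The highest split in all of these set WT replicates 1 and 3 and TG replicate 1 against the remaining arrays. It was picked after its counts were seen and lies along the first principal component, the axis of most variance, so its counts describe how the arrays differ and do not test a cause.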
